A study of Mus musculus with 2 samples.

How the data were processed

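Total RNA depleted of ribosomal RNA was sequenced from the nucleoplasmic fraction of bone marrow-derived macrophages of C57BL/6J mice, which are macrophages grown from marrow precursors in culture. Per the labels, the cells had been exposed to Lipid A, the part of bacterial lipopolysaccharide that Toll-like receptor 4 recognises, at 100 ng/ml for 12 h, then kept without it for 12 h, and were taken at 0 min of a renewed exposure. The 2 libraries are biological replicates 1 and 2 of this 1 group, from separate biosamples of the same strain. Starting RNA was 1 µg for replicate 1 and 500 ng for replicate 2, and the labels give a size range of 250 to 400 for both. No other group was analysed here, so no test between conditions was made, and the starting amount cannot be told apart from the replicate number.

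The deposited gene-level tables give an expected count and a TPM, a transcript abundance scaled to a fixed total per library, per gene, and the deposited transcript-level tables give the same units per transcript. A further deposited transcript-level table per library, called the second quantification here, holds estimated counts and TPM. Per the deposited notes beside the files, the gene-level values derive from alignments to the transcriptome, the second quantification derives straight from the reads, the assembly is mm10 and the annotation is the GENCODE mouse release 21. The quantification programs, their versions and the use of strand in counting are not given in the sources used here. For this reason, values of antisense genes, overlapping genes and near-identical copies are uncertain.

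All 55536 genes of the gene-level tables matched the GENCODE annotation of GRCm38, which gave symbols, gene types and positions. Expected counts over these genes summed to 22907877 in replicate 1 and 18612405 in replicate 2, and estimated counts of the second quantification to 30419009 and 32279044. A further 26345 entries per library name no annotated gene. They held 1.01% of the expected counts of replicate 1 and 0.336% of those of replicate 2 and were kept out of library sizes. The second quantification has no value for 86 genes, which were left out wherever it was used.

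Expected counts were rounded to whole numbers. Log2 ratios of replicate 2 over replicate 1 used TMM scaling factors from edgeR 4.0.16 in R 4.3.3, estimated on the 14892 genes past filterByExpr, with a prior count of 0.5. The biological coefficient of variation is the square root of the common dispersion that edgeR estimated with an intercept as the only term. DESeq2 1.42.0 gave an alternative. Genes called apart had an absolute log2 ratio of at least 1 and a mean count of at least 100, whether or not they passed filterByExpr. Because each ratio sets 1 library against 1 other, no p-value was computed. Intervals on ratios are exact (Clopper-Pearson) 95% intervals of the 2 counts. Intervals and the floor of 3 counts used for genes at 0 cover counting error only, since reads carried no molecular identifiers that the files show.

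Levels of gene lists are medians of log2(TPM + 0.1), given as the mean and SD of the 2 libraries. The 26 lists, the named-gene rule, the comparisons and most alternatives were set before the data were examined. The rule took the 3 members with the highest mean TPM and the lowest member of each list (for other cell types, only the highest), the 15 genes with the highest mean TPM among all genes, and the 5 largest log2 ratios each way between libraries. The list members Aldoa, Ddit3 and Rmrp, were left out of their lists because 2 annotated genes share the symbol. Medians were taken over protein-coding members, which leaves out Mx2 and Ighm. Each of the 24 lists of protein-coding genes was set against 10000 random lists of its size drawn from 22028 protein-coding genes, and called above or below them past the 95th or 5th percentile, tied lists sharing ranks in the printed percentile. Genes are not replicates, so a percentile describes these libraries and is not a p-value. Between libraries, random lists were matched on mean expression in 20 bins. The retained-intron share is the part of a gene's transcript TPM assigned to transcripts annotated as retained introns. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

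The replicate measures were tested on simulated data with the means and totals of these libraries over 55536 genes. With a simulated coefficient of 0.1 and no changed gene the estimate was 0.101, and 1 gene passed the rule for genes apart; with 0.3 the estimate was 0.296 and 1180 genes passed. At the coefficient of these libraries, 0.186, a simulation added after the data were seen put 114 unchanged genes past the rule. Of 200 genes changed 4-fold between replicates 1 and 2, the rule for genes apart took 94% at a coefficient of 0.1, with 0 unchanged genes, and 88% at 0.3, with 1150 unchanged genes. Of 200 genes changed 2-fold, which is the threshold of the rule, it took 43.5% at 0.1 and 43% at 0.3. Alternatives covered the scaling, the count filter, the quantification, the TPM denominator, the pseudocount, detection minimums, the choice of random lists and leaving out either replicate where a value needs only 1 library.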

Results

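Nucleoplasmic RNA of macrophages held 12 h without Lipid A after 12 h of exposure was profiled in 2 biological replicates. The series has 1 group, so levels, contrasts between gene groups within the same libraries and the agreement of the replicates are described, with no comparison between conditions. Expected counts over annotated genes totalled 22907877 in replicate 1 and 18612405 in replicate 2. At a TPM of at least 1 in both libraries, 12462 genes were detected, 9791 of them protein-coding.

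Small structured RNAs took a large part of TPM in the gene-level tables, and the nuclear long noncoding RNA Malat1 a large part of expected counts. Rn7sk, the RNA of the 7SK ribonucleoprotein that holds back transcription elongation (ENSMUSG00000065037.1, mm10 chromosome 9, 78175303 to 78175633), had the highest mean level in the gene-level tables, 288326 ± 13702 TPM (SD, n = 2), and 95022 and 142353 TPM in the second quantification. It was followed by Rpph1, the RNA of ribonuclease P, at 61194 ± 27453 TPM, and by Rmrp, the RNA of ribonuclease MRP, at 61125 ± 15826 TPM for its ribozyme entry. Another Rmrp entry, a lincRNA at the same place, had 11154 ± 9365 TPM, and the split of reads between the pair is uncertain. The signal recognition particle RNAs Rn7s1 and Rn7s2 had identical values of 41267 ± 12437 TPM, so that reads of these near-identical copies cannot be separated. Malat1 (chromosome 19, 5795690 to 5802672) held 10.7% ± 0.671 of expected counts (SD, n = 2) and 22797 ± 5007 TPM. Its share of counts was lower in replicate 2 (11.2% against 10.2%) but its TPM was higher there (19257 against 26338), so its TPM spread is uncertain. The remaining genes among the 15 highest were mt-Atp8 at 20637 ± 17314 TPM, mt-Co1 at 14315 ± 5175 TPM, the snRNA genes Gm22513, Gm25939, Gm23849 and Gm24950, the snoRNA Gm22988, and Gm28661, a nuclear copy of mitochondrial sequence on chromosome 1. All 15 were lower in the second quantification in both libraries, by several-fold for some: mt-Atp8 had 1399 and 9542 TPM there, against 8394 and 32879 in the gene-level tables, and Gm22513 had 994.6 and 1807 TPM, against 15239 and 14258. TPM divides by effective length, which is short for these RNAs: Gm22988 reached 6972 ± 1260 TPM from 332 and 517 counts. The second quantification gave Gm22988 only 157 TPM in replicate 1 and 440 TPM in replicate 2, so its level and rank are uncertain. Protein-coding genes held 76.2% ± 0.490 of expected counts but 28.5% ± 1.44 of TPM, while Rn7sk held 4.19% ± 0.711 and 28.9% ± 1.35.

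Among long noncoding RNAs, 17 of 20 members were at a TPM of at least 1 in both libraries. Neat1, the scaffold of paraspeckles, had 875 ± 109 TPM and Xist 161 ± 4.72 TPM (SD, n = 2). Rian had no count in either library of the gene-level tables, but the second quantification put it at 4.42 TPM in replicate 1 and 6.67 TPM in replicate 2, so its level is uncertain. In the structured noncoding list 8 of 11 members reached a TPM of 1 in both, and Rny3 had no count. The effective length of Rny3 in the gene-level tables allows no limit on its TPM, and the second quantification gave 5.73 and 6.79 TPM, so its level is uncertain. An annotated retained-intron transcript was found for 6143 protein-coding genes at a TPM of at least 1 in both libraries. Over these genes, the median share of transcript TPM assigned to such transcripts was 30.0% ± 1.02 (SD, n = 2). The share passed 50% in both libraries for 949 of these genes. Over the summed transcript TPM of all protein-coding genes, retained-intron transcripts took 17.2% ± 1.09, and here replicate 1 was higher (18.0% against 16.5%), while in the median over genes replicate 2 was (29.2% against 30.7%).

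Genes that mark macrophages were high and those of other cell types low. All 20 macrophage identity genes were at a TPM of at least 1 in both libraries and 19 at a TPM of at least 10. The highest were Lyz2, a lysozyme, at 1247 ± 172 TPM (chromosome 10, 117277331 to 117282321), the protease gene Ctss at 870 ± 332 TPM and Mpeg1, which encodes perforin-2, at 736 ± 97.5 TPM. The lowest was the transcription factor gene Cebpa at 10.4 ± 0.707 TPM. Of 74 markers of other cell types, 64 were under a TPM of 1 in both libraries. The highest per list were Csf3r at 76.6 ± 14.3 TPM for neutrophils, Cd4 at 21.1 ± 0.771 TPM for T and NK cells, Pf4 at 14.6 ± 2.95 TPM for the erythroid and megakaryocyte list, Batf3 at 4.71 ± 3.22 TPM for dendritic cells, Acp5 at 4.22 ± 2.48 TPM for osteoclasts, Ighm at 1.08 ± 0.212 TPM for B cells, Kit at 0.805 ± 0.460 TPM for mast cells and Col1a2 at 0.090 ± 0.042 TPM for stromal cells. The median of macrophage identity genes exceeded that of other cell types by 9.55 ± 0.71 on the log2(TPM + 0.1) scale (SD, n = 2), above all random pairs of lists.

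Interferon-stimulated genes were abundant, while inflammatory effector genes ranged from high levels to no count. Of 29 interferon-stimulated genes, 28 were at a TPM of at least 10 in both libraries. Rsad2, which encodes the antiviral enzyme viperin, had 882 ± 290 TPM (SD, n = 2; chromosome 12, 26442746 to 26456452), Ifit2 748 ± 119 TPM and Mx1 655 ± 299 TPM. The lowest was the chemokine gene Cxcl9 at 0.460 ± 0.453 TPM, from 57 and 9 counts. Of 21 inflammatory effector genes, 11 were at a TPM of at least 1 in both, 4 at a TPM of at least 10 and 6 under 1 in both. The chemokine genes Ccl5 (chromosome 11, 83525778 to 83530518), Ccl3 and Ccl4 led with 679 ± 254, 112 ± 16.2 and 112 ± 36.4 TPM. Csf2 had no count, which allows up to 0.183 TPM in replicate 1 and 0.209 TPM in replicate 2. Such limits hold for the counts of the gene-level tables. The median of interferon-stimulated genes lay 6.25 ± 0.22 above that of inflammatory effectors (log2 scale, SD, n = 2), beyond the 95th percentile of random pairs at 4.03.

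Genes of antimicrobial defence and of feedback on inflammatory signalling were mostly expressed. Of 17 antimicrobial and receptor genes, 14 were at a TPM of at least 1 in both libraries. The acute-phase gene Saa3 had 2168 TPM in replicate 1 and 542 TPM in replicate 2 (chromosome 7, 46711998 to 46715700), Acod1, which encodes the itaconate-producing enzyme, 201 ± 17.7 TPM, and the scavenger receptor gene Msr1 117 ± 16.5 TPM. Camp had no count, and the second quantification gave 0.276 TPM in replicate 1 and 0.165 TPM in replicate 2. Of 21 negative regulators, 20 were at a TPM of at least 1 in both, led by Trim30a at 189 ± 4.31 TPM, Inpp5d at 82.6 ± 23 TPM and Nfkbia, which encodes the inhibitor of NF-kappaB, at 55.3 ± 16.2 TPM. The lowest was Sigirr at 0.185 ± 0.00707 TPM. The median of antimicrobial genes was 4.06 ± 0.85 above that of inflammatory effectors, at percentile 93.1 of random pairs. The median of inflammatory effectors minus that of negative regulators was -2.86 ± 0.28, at percentile 14.2. Both differences exceeded the SD between libraries and neither lay outside the random pairs. With members limited to a TPM of at least 0.1 in both libraries the latter difference was -1.66.

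Most genes of the receptor pathway, antigen presentation, metabolic, stress response, ribosomal protein and mitochondrial lists were detected. All 24 genes of Toll-like receptor 4 signalling were at a TPM of at least 1 in both libraries, from Tbk1 at 59.1 ± 0.368, Nfkb1 at 43.6 ± 2.52 and Tab2 at 42.6 ± 1.57 TPM to Tirap at 3.40 ± 0.594 TPM (SD, n = 2). All 15 antigen presentation genes passed that level, with the class I genes H2-K1 at 2348 ± 365 TPM and H2-D1 at 1453 ± 533 TPM, B2m at 747 ± 98.4 TPM and the class II transactivator gene Ciita lowest at 5.38 ± 1.51 TPM. All 15 glycolysis genes did as well, led by Hk3 at 186 ± 52.7, Pkm at 114 ± 18.6 and Ldha at 45.1 ± 1.25 TPM, with Slc2a1 lowest at 2.62 ± 0.134 TPM. In the lipid and sterol list 18 of 19 did, with Apoe at 567 ± 422, Fabp5 at 208 ± 84.1 and Lpl at 99.0 ± 58.5 TPM, and Ch25h at 0.315 ± 0.148 TPM. In the stress response list 11 of 13 did, with Hspa5 at 147 ± 29.2, Sqstm1 at 125 ± 37.1, Atf4 at 65.0 ± 4.40 and Hspa1b at 1.01 ± 0.792 TPM. Of 85 cytosolic ribosomal protein genes 82 did, with Rps24 at 137 ± 1.24, Rpl41 at 121 ± 6.91 and Rpl10 at 91.9 ± 14.7 TPM. Rpl3l had no count, and the second quantification gave 0.258 and 0.0910 TPM. All 13 mitochondrial mRNAs were at a TPM of at least 10, with mt-Nd6 at 5505 ± 936 TPM and mt-Co2 lowest at 152 ± 111 TPM. The difference of mt-Co2 between the libraries had the opposite sign in the second quantification, so its level and rank are uncertain.

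A smaller part of the immediate early, alternative activation, proliferation and histone lists reached a TPM of 1 in both libraries. More members had enough counts to pass filterByExpr: 18 of 18 immediate early, 8 of 14 alternative activation, 18 of 20 proliferation and 46 of 68 histone genes. At a TPM of at least 1 in both libraries were 12 of 18 immediate early genes, with Klf6 at 82.9 ± 8.85, Atf3 at 36.1 ± 14.1, Junb at 35.7 ± 13.5 and Fosb at 0.20 ± 0.028 TPM (SD, n = 2). The same held for 6 of 14 alternative activation genes, with Stab1 at 190 ± 43.0, Tgfb1 at 66.0 ± 0.870 and Mrc1 at 39.4 ± 15.3 TPM, while Ccl17 had no count, which allows up to 0.369 and 0.409 TPM. Of 20 proliferation genes 10 did, with Pcna at 22.7 ± 0.841, Ccnd1 at 10.1 ± 1.12, Mcm6 at 7.17 ± 0.198 and Ccnb2 at 0.110 ± 0.113 TPM. Of 68 replication histone genes 41 did, with Hist3h2a at 36.1 ± 11.4, Hist2h2aa2 at 35.5 ± 20.9 and Hist1h4m at 24.8 ± 7.18 TPM, while Hist1h2aa had no count, which allows up to 0.651 and 0.694 TPM. Histone genes are near-identical copies, so their single values are uncertain.

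Of the 24 protein-coding lists, 11 had medians above random lists: macrophage identity, Toll-like receptor 4 signalling, negative regulators, antimicrobial, interferon-stimulated, antigen presentation, glycolysis, lipid and sterol, stress response, mitochondrial mRNA and ribosomal protein genes. The inflammatory effector list lay at percentile 75, immediate early genes at 93.0, replication histones at 94.8, proliferation at 69.6 and alternative activation at 61.9. The 8 lists of other cell types lay between percentiles 5.17 and 44.5. The calls of negative regulators and stress response depend on the background: against protein-coding genes at a TPM of at least 1, neither was above random lists. With genes at 0 counts left out, stress response was not above them either. Without replicate 2, immediate early genes and replication histones were also above, and so were the histones against random lists matched on length. No list was below random lists, but for 17 lists the 5th percentile equals the value of a TPM of 0, so that this outcome could not occur for them. For the other lists it was at most -2.70, close to that value of -3.32, so the outcome was hardly within reach. With genes at 0 counts left out of lists and background, the T and NK cell and mast cell lists had too few members left and 22 lists were compared. Of these, 8 were below: proliferation, replication histones and, among other cell types, the neutrophil, dendritic, stromal, B cell, erythroid and megakaryocyte, and osteoclast lists. Against protein-coding genes at a TPM of at least 1, 13 lists were below. They were the 8 lists of other cell types and inflammatory effectors, immediate early genes, replication histones, proliferation and alternative activation. Only other cell types and alternative activation had medians under that level, where a fall below was fixed. The remaining lists also kept members under it, which the background left out, so this setting favoured their fall below.

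**Figure D1:**
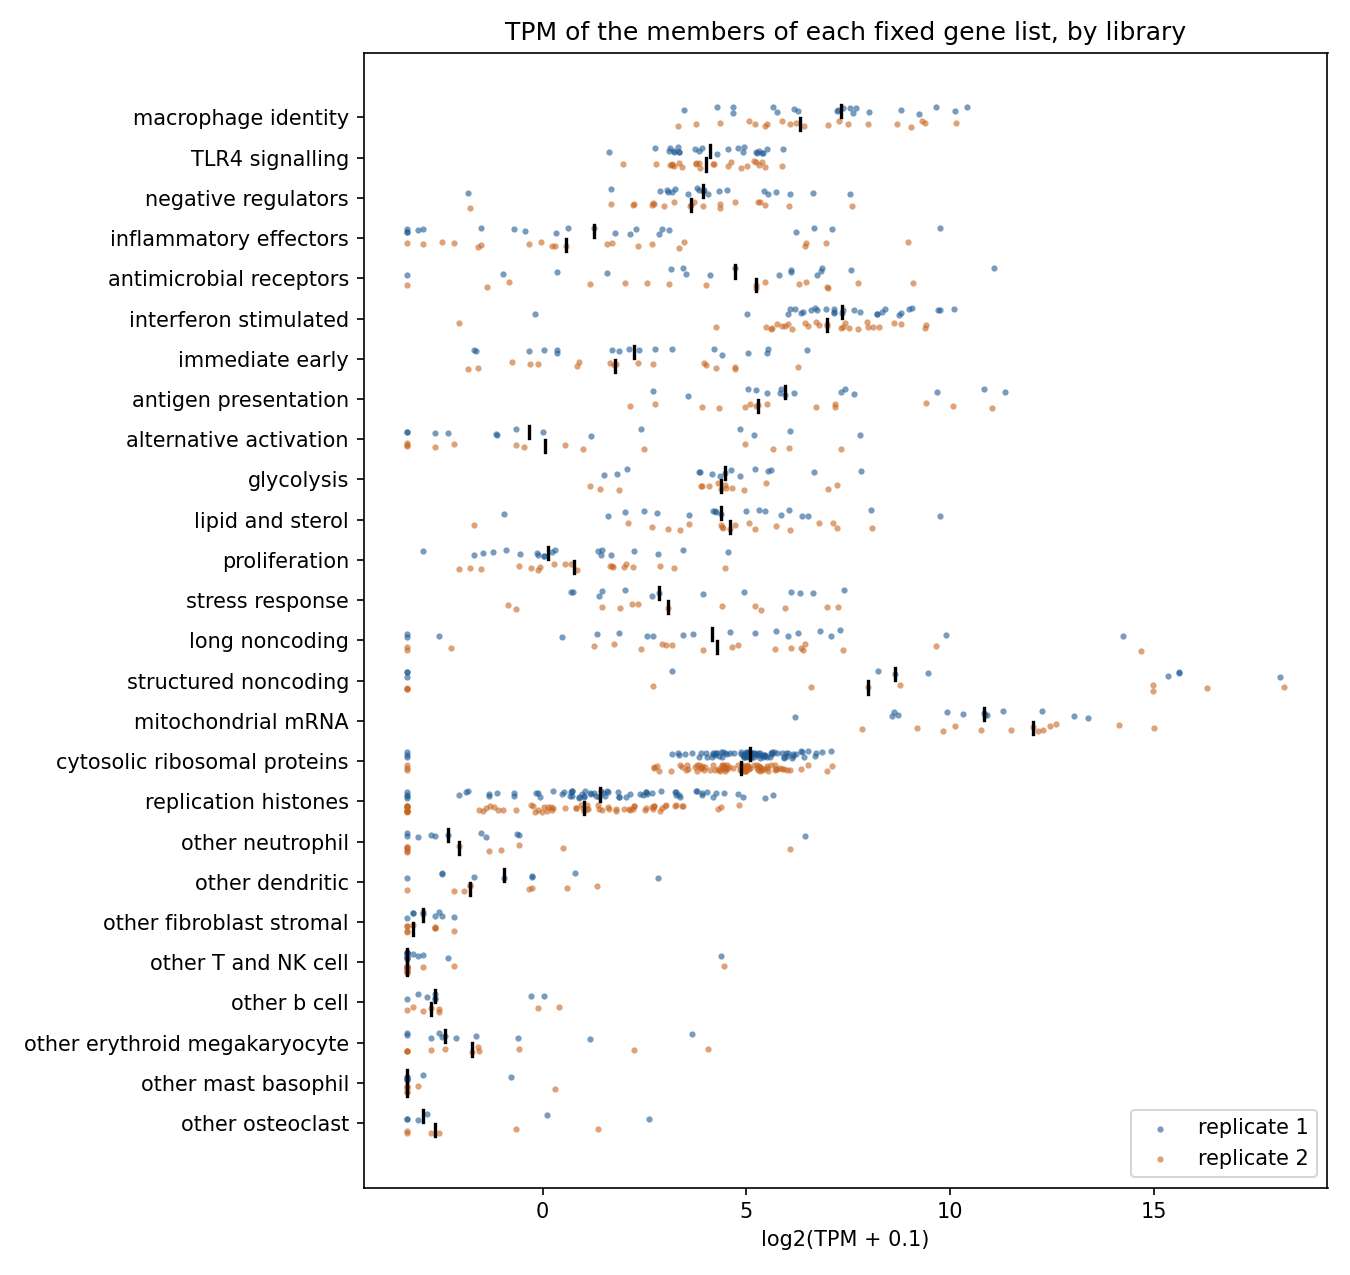
Each point is a member of a fixed gene list, at its log2(TPM + 0.1) in replicate 1 (blue) or replicate 2 (orange), and black bars are the list medians per library. Interferon-stimulated genes have a mean median of 7.17 and inflammatory effectors one of 0.92, while points at the left edge are genes listed at a TPM of 0.

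The replicates differed beyond counting error. The chi-square of their counts over 14892 genes was 70.6 per degree of freedom, so they are not 1 library deposited again. The log2 ratio of replicate 2 over replicate 1 had an SD of 0.47 over these genes, and the biological coefficient of variation was 0.186. Of 10198 genes with a mean count of at least 100, 204 were apart by a log2 ratio of at least 1 in absolute size, 84 higher and 120 lower in replicate 2. In counts simulated with a coefficient of 0.186 for every gene and no changed gene, 114 of 10186 passed the same rule. With library totals alone as scaling 99 were higher and 99 lower. The second quantification put 500 of 15106 genes past this rule, 306 higher and 194 lower. Of the 204 genes, 203 had a value there, 199 had the same direction and 123 passed the rule again. A mean count minimum of 50 gave 330 genes apart. These are differences between 2 libraries with no replicate check.

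The genes lowest in replicate 2 by the rule were Gm49342 (726 against 0 counts), B430305J03Rik (362 against 0) and Gm26759 (253 against 0). Gm49342 overlaps Pnp on the same strand, and the other two lie antisense to Rap2b and Irf2bp2, so the assignment of these reads is uncertain. In the second quantification Gm49342 had 24.2 TPM in replicate 1 and 7.35 TPM in replicate 2, a log2 ratio of -2.12, Gm26759 had a log2 ratio of -2.57, and B430305J03Rik was listed at 0 TPM in both libraries. No fold is given for genes at 0 counts in 1 library, since the assignment of their reads is uncertain. They were followed by the rRNA entry CT010467.1, with a log2 ratio of -3.14 (95% counting interval -3.24 to -3.04) that was -1.42 in the second quantification, and by Snora73b, a snoRNA within Rcc1 and Snhg3, with -2.87 (-3.33 to -2.46), or -2.33 in the second quantification. CT010467.1 overlaps the lincRNA Gm42418 on the other strand, which had 46332 counts in replicate 1 and 15433 in replicate 2. Highest in replicate 2 were Gm43302 (0 against 241 counts), which overlaps Gbp6 and Gbp10, and an entry of Nnt (0 against 234 counts), which overlaps another entry of that symbol. The second quantification listed Gm43302 at 0 and 1.17 TPM and this Nnt entry at 0.0457 and 1.13 TPM. Summed over both Nnt entries, counts were 513 in replicate 1 and 481 in replicate 2. Gm43302 and Gbp10 together had 388 and 391 counts, and Gm43302 and Gbp6 together 12699 and 9285. Scd1, a stearoyl-CoA desaturase gene (chromosome 19, 44394455 to 44407879), had a log2 ratio of 3.56 (3.08 to 4.11) from 36 and 360 counts. The cystine transporter gene Slc7a11 had 2.91 (2.54 to 3.33) and mt-Atp8, which overlaps mt-Atp6, had 2.32 (2.27 to 2.37). In the second quantification the log2 ratio was 3.34 for Scd1, 1.56 for Slc7a11 and 2.34 for mt-Atp8.

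Whole lists also differed between the libraries, a comparison chosen after the data were seen. In the gene-level tables the 13 mitochondrial mRNAs were all higher in replicate 2, with a median log2 ratio of 1.28, and 9 of them passed a ratio of 1. The second quantification gave a median of 1.27, with mt-Co2 lower in replicate 2 at -0.52 (1.72 in the gene-level tables) and mt-Co3 at 0.06 (1.28). Interferon-stimulated genes were lower in replicate 2 for 27 of 28 tested members, with a median of -0.61, and antigen presentation genes for 15 of 15, with -0.62. Immediate early genes were lower for 15 of 18, with -0.44, macrophage identity genes for 19 of 20, with -0.34, negative regulators for 15 of 20, with -0.30, and antimicrobial genes for 9 of 14, with -0.24. Ribosomal protein genes were lower for 67 of 82, with -0.29, and replication histones for 36 of 46, with -0.58. Beside mitochondrial mRNAs, the lists with medians above the 95th percentile of random lists were inflammatory effectors at 0.26, proliferation at 0.21 and lipid and sterol genes at 0.19, with 9 of 15, 13 of 18 and 10 of 18 members higher. Each of the medians given so far lay outside the 5th to 95th percentile of random lists matched on expression, and each kept its sign in the second quantification. Within that range lay the Toll-like receptor 4 signalling list at 0.02, stress response at 0.04 and glycolysis at -0.0007. Alternative activation at -0.15 and the dendritic cell list at -0.19 also lay within it. Genes of a list may vary together, which random lists do not reproduce, so a median outside them is not a test. Library totals shift the ratios of all genes alike, by 0.04, so the choice of scaling does not test these signs. In the second quantification inflammatory effectors had a median of 0.095 and proliferation one of 0.18, under the gene-level 95th percentiles of 0.19 and 0.20.

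**Figure D2:**
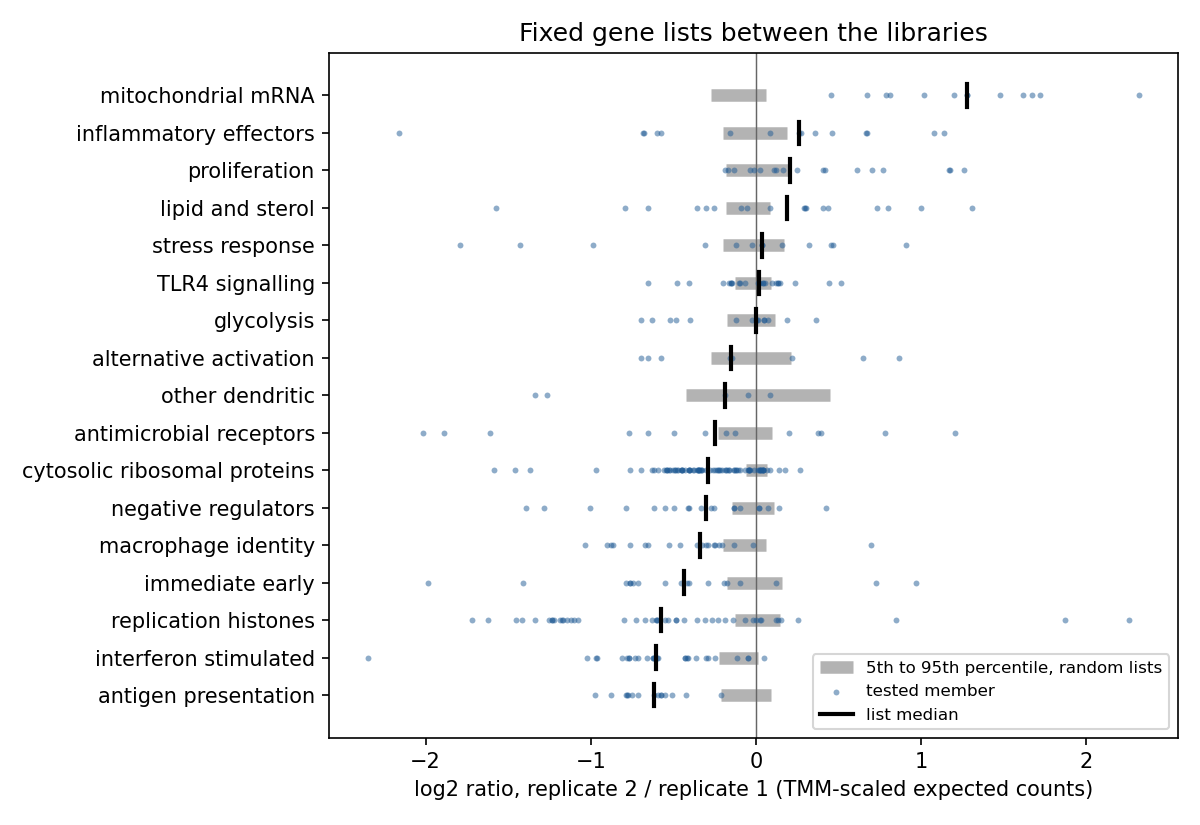
Log2 ratio of replicate 2 over replicate 1 (TMM-scaled expected counts) for the tested members of each fixed protein-coding list with at least 5 tested members. Grey bars span the 5th to 95th percentile of medians of 10000 expression-matched random lists and black bars are list medians, from -0.62 for antigen presentation to 1.28 for mitochondrial mRNAs.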

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

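The tests on read assignment between quantifications, on starting RNA, on nuclear copies of mitochondrial sequence, on mitochondrial rRNA and on rescaled TPM were chosen after the result was seen. The patterns were noticed in these data and tested on the same data. The design has 1 group, so no biological explanation was tested.

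Entries outside the gene annotation held reads. The phiX control genome, a sequencing control, had 233489 expected counts in replicate 1, a share of 1.01% (95% Wilson interval 1.00 to 1.01), and 62782 in replicate 2, a share of 0.336% (0.334 to 0.339). The 26248 entries with only a numeric identifier summed to 24 counts in replicate 1 and 52 in replicate 2, a sum that says nothing of any single entry. The 96 ERCC spike-in entries had 0 counts in both.

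Interferon-stimulated genes were lower in replicate 2, with a median log2 ratio of -0.61. Antigen presentation genes and replication histones were as low or nearly so, with medians of -0.62 and -0.58. Immediate early, macrophage identity and negative regulator genes were also lower, with medians of -0.44, -0.34 and -0.30. Only the interferon list was tested further. After a trend on GC content, transcript length and mean level was removed its median was -0.42, under all matched random lists. This argues against that trend as the whole cause. The second quantification gave -0.57, against an origin in read assignment. More mature cytoplasmic mRNA in replicate 1 would lower ribosomal protein genes as far, but their median lay 0.32 above that of the list, beyond the half-range of 0.12 of random lists; since ribosomal protein genes were also lower, by a median of -0.29, a partial share of this explanation stays open. Starting RNA amount or another difference between the cultures remains open, as there is 1 library per starting amount.

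Mitochondrial mRNAs were higher in replicate 2, with a median log2 ratio of 1.28 (1.27 in the second quantification, where mt-Co2 was lower at -0.52). More cytoplasm in that nucleoplasmic fraction would raise ribosomal protein genes, whose median log2 ratio was -0.29, against this explanation as the whole cause. Several other protein-coding lists were also lower in replicate 2 and some were higher. Such shifts could hide a partial share, which stays open. Moving reads between mitochondrial genes and their 7 copies on chromosome 1 would leave the sum of both level, but that sum had a log2 ratio of 1.03. Whole mitochondria carried over with the nuclei could not be told apart from other origins: mt-Rnr2 had a log2 ratio of -2.33, but ribosomal depletion removes this RNA and may have differed between the libraries. Other rRNA entries were lower in replicate 2 too, mt-Rnr1 at -1.25 and the nuclear CT010467.1 at -3.14, so unequal depletion stays open.

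Protein-coding TPM was lower in the second quantification, with a median log2 ratio to the gene-level tables of -0.82 in replicate 1 and -0.41 in replicate 2. There miRNA entries took 51.5% of TPM in replicate 1 and 19.4% in replicate 2, and processed pseudogenes took 11.1% and 24.4%. Short non-coding targets taking the TPM total may account for this, and after rescaling to protein-coding genes the median farther from 0 was 0.068. Equal totals push this value towards 0 whatever the cause, so the test decides nothing.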

How the results depend on the processing

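A value moved under 22 alternatives. A count moved if it differed by over 1.5 times, a contrast or share if by more than its SD between libraries, a list ratio if by more than the half-range of random lists, and the spread and coefficient if they differed when rounded to 2 decimals. Leaving out 1 of 2 replicates moves a contrast or share by less than its SD by construction, and other scalings shift the ratios of all genes alike, by 0.04 for library totals and less for DESeq2 size factors, too little to move a list ratio; neither tests stability. In the second quantification no called list ratio changed sign. The protein-coding restriction and the list ratios were chosen after the data were seen; no cause was tested unless stated. No paired analysis was possible because there is 1 group. Spread, coefficient of variation and genes apart need both libraries, so none could be left out. Depth limits the genes with few counts, down to the floor of 3 counts. With the second quantification the spread was 0.52, the coefficient 0.213, genes apart 500, lists below random lists 1, the retained-intron share 35.0%, inflammatory minus negative regulators -2.47, interferon minus inflammatory 5.54 and macrophage minus other cell types 8.22. Without the count filter the spread was 0.68 and the coefficient 0.205, and DESeq2 gave a coefficient of 0.217. A mean count minimum of 50 gave 330 genes apart, as more genes enter. Lists below random lists numbered 13 against genes at a TPM of at least 1, where any list with a median under that level must fall below. Inflammatory effectors, immediate early genes, proliferation and replication histones were among them with medians above that level. In the same order, 11 of 21, 12 of 18, 10 of 20 and 41 of 68 members reached it in both libraries. The members under it stayed in the lists while the background left such genes out, so the setting itself favoured a fall below. With genes at 0 left out, 8 lists were below. That setting removes the floor at a TPM of 0 and also changes lists and background. For proliferation and replication histones the 5th percentile lay above that floor before, but only at -3.26 and -2.84 against -3.32. A fall below was thus hardly within reach before. In the same order of contrasts, pseudocount 1 gave -2.38, 5.68 and 6.76, and members at a TPM of at least 0.1 gave -1.66, 5.05 and 7.0, with antimicrobial minus inflammatory at 3.13. Rescaling TPM to protein-coding genes moved macrophage minus other cell types to 10.48. Lists above random lists numbered 9 to 13 over the alternatives. Genes detected numbered 14189 at a TPM of at least 0.5, 14970 at a count of at least 10, 15418 with rescaled TPM and 15437 in the second quantification. Leaving out a replicate gave 13159 to 13161 genes detected and 11 to 13 lists above random lists.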

Other observations

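Single genes of lipid metabolism differed between the replicates in both directions; those named here were chosen after their values were seen. The desaturase genes Scd2 and Fads2 had log2 ratios of 1.27 (95% counting interval 1.23 to 1.31) and 2.00 (1.72 to 2.30), the elongase gene Elovl6 1.90 (1.5 to 2.32) and the lipoprotein lipase gene Lpl 1.31 (1.27 to 1.36). In the second quantification Elovl6 had 1.11. Apoe at -1.58, Fabp5 at -0.65 and Fabp4 at -0.30 were lower in replicate 2, and Srebf1 had -0.05. The whole lipid and sterol list had a median of 0.19, with 10 of 18 members higher.

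Ifnb1, the gene of interferon beta, had 50 counts in replicate 1 and 9 in replicate 2, a log2 ratio of -2.16 (-3.43 to -1.18). Other genes of the inflammatory effector list, also chosen after their values were seen, went both ways: Ccl5 had a log2 ratio of -0.67, Ccl4 -0.60, Nos2 -0.57 and Edn1 -0.68, while Il6 had 1.08 from 24 and 43 counts and Il12b 1.14 from 30 and 56 counts. Inflammatory effectors as a list had a median log2 ratio of 0.26, at percentile 99.0 of matched random lists, but 0.095 in the second quantification, under the 95th percentile of those lists at 0.19. Negative regulators had -0.30, and -0.29 in the second quantification.

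The processed pseudogenes Gm12895 and Gm12896 each had 52596 TPM in replicate 1 and 117999 TPM in replicate 2 in the second quantification and 0 counts in the gene-level tables.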
